A study of Mus musculus with 4 samples.

How the data were processed

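Total RNA of hepatic macrophages was extracted with TRIzol, purified on columns, amplified and labelled with biotin with the GeneChip WT Pico kit, per the labels' protocols. The deposited values are log2 signals per probe set, made by the authors with RMA (robust multi-array average, which usually comprises background correction, quantile normalisation and a summary over the probes of a set) in Affymetrix Expression Console, per the submitters' processing notes. Versions, annotation release and options are not given in the sources used here. The log2 scale was taken from the usual output of RMA and from the values, which ran from 2.34 to 19.9 with medians near 6.2. The upper end of the distribution differed between arrays, so the arrays did not share a single distribution after the authors' processing. At the highest value stood 213 and 208 probe sets in fractions m and p after anti-CCL3 antibody and 207 and 145 after isotype control, and differences between such probe sets are lower bounds.

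The table held 72688 probe sets on each of 4 arrays, of which 65956 were transcript clusters, 5222 negative controls and 1324 positive controls. Hybridisation controls, which are added in rising amounts, stood in that order (bioB, bioC, bioD, cre) on each array. Genes were named through the platform's annotation: 30604 transcript clusters had exactly 1 symbol, 2146 had several and 33206 had none listed, and 827 symbols were updated through the gene number. Clusters with several symbols or none were left out of gene-level tests. Of 30294 named clusters with a chromosome in the RefSeq gene table, 30010 lay on the chromosome that the cluster's identifier gives. The brightest cluster lay on another chromosome, or on none, for 171 genes, 140 of them tested, and such clusters may read related sequences. No genomic coordinates were used.

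For each of 30142 genes the probe set with the highest mean over 4 arrays was kept, and genes at or above the median of these means, 6.16, were tested, which left 15071 genes, 8316 of them protein-coding. Some genes share the same values on all arrays, and the tested genes held 14778 distinct profiles. The deposited values were used without further normalisation. limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table for input, fitted antibody and fraction as additive terms on all 4 arrays with empirical Bayes moderation. This leaves 1 residual degree of freedom, which holds the interaction together with noise, and the prior added 1.69. The p-values were adjusted with Benjamini-Hochberg at 0.05. Differences are log2 differences, anti-CCL3 minus isotype control or fraction p minus fraction m, with limma's standard errors, whose median was 0.13. The prior keeps these errors from falling much below 0.11. Errors near 0.11 are therefore set by the prior and are not a measured spread between arrays. Naming genes by agreement of both pairs also favours small errors. The fraction term pairs the arrays of a fraction across antibody groups. Differences within a fraction or an antibody group come from 1 array on each side and were not tested.

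Gene lists, 39 in number, covered macrophage populations, other liver, blood and tumour cell types, chemokines, lymphangiogenesis, activation states and housekeeping functions. Of these, 38 had 3 or more tested members and were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, fry and medians against 10000 random lists of equal brightness as alternatives. Of 649 list genes, 578 had a probe set of their own and 276 were tested. The list of liver sinusoidal endothelial cell markers had 1 tested member and was not tested.

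Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, for each contrast and direction, 12 genes past the threshold with the largest value of the smaller of both paired differences, both in the same direction, filled up with genes that did not pass and are named as such. Symbols of predicted genes, pseudogenes, olfactory and vomeronasal receptors and small RNAs with the usual prefixes were passed over. Small RNAs without these prefixes, such as mmu-mir-6371, remained. So did the receptor segments Traj14, Traj1 and Igkv13-87, which the RefSeq gene table lists as pseudogenes, since the rule went by symbol. The rule also took 6 genes per pattern of opposite antibody differences, Ccl3, Ccr1, Itgam and Adgre1, and the 2 highest and 2 lowest members of each list discussed. Another gene that the rule named is not reported here. Which lists to discuss was chosen after their values were seen, as were the sets of abundant leukocyte transcripts, of Y-linked genes, of olfactory receptors and of mitochondrial probe sets, and the genes quoted from them. The Y-linked genes with many copies are Sly and predicted protein-coding genes of the Y chromosome, a class known for many copies, and copies were not counted here.

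The fits were tested on simulated data with 15071 genes and 5 runs per contrast. Simulated genes were independent, with variances drawn from the fitted prior, and the simulated arrays had no differences in scale. A rate near the nominal one for unchanged genes is therefore set by the simulation and does not show that the test holds on these arrays. Unchanged genes had an unadjusted p (limma) below 0.05 in 5.03% for antibody and 5.19% for fraction. At an adjusted p of 0.05 the share of changed genes recovered at a log2 difference of 8 was 89.2% for antibody and 91.6% for fraction. A list of 10 genes shifted by 1 on the log2 scale was called by camera in 5 of 5 runs for each contrast. Over the same 5 runs, lists without a shift were called 1 time for fraction and 0 times for antibody. The tested lists had medians of smaller size, from -0.31 to 0.15 over both contrasts. The simulation therefore does not show how often shifts of that size would be called. Alternatives were the filter on dim genes, quantile normalisation, median centring, the mean over a gene's probe sets, a trended or robust prior, all probe sets, the tested factor alone in the fit, and each array left out in turn. Cyclic loess normalisation, protein-coding genes alone and leaving out clusters on another chromosome than the gene were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.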

Results

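The arrays measured RNA of hepatic macrophages from livers of male C57BL/6J mice carrying a disease model that the labels call CRCLM, in a series on VEGFC and the spread of colorectal cancer in the liver. Treatment was either an antibody against CCL3, a chemokine that attracts monocytes and macrophages, or an isotype control antibody, which is of the same antibody class but is not directed against CCL3. Each antibody group was represented by 2 arrays, of cell fractions whose names combine F4/80 and CD11b, surface proteins of macrophages and myeloid cells, with the letter m or p. The labels do not spell out these letters, so the fractions are called m and p. Each combination of antibody and fraction had 1 array, so values within a combination have no replicate error, and the number of arrays limits the precision of every comparison. Nothing in the labels says whether the arrays came from separate animals. The p-values therefore measure only the spread left in these 4 arrays, in part pooled over genes through the prior. The median signal of the transcript clusters was 6.21 and 6.18 on the log2 scale in fractions m and p after anti-CCL3 antibody, and 6.18 and 6.18 in fractions m and p after isotype control. The 99th percentile was 15.6, 15.2, 15.2 and 14.5 in the same order, so the isotype control array of fraction p was the dimmest at the bright end.

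Transcripts that macrophages make in abundance had signals in the range of the negative-control probe sets. The median over 20 such transcripts was 5.96, against 6.34 for 5222 negative controls. Among them, Actb, which encodes beta-actin, stood at 6.58, the lysozyme gene Lyz2 at 6.17, B2m, the light chain of MHC class I, at 5.76 and Csf1r, the receptor for macrophage colony-stimulating factor, at 5.38, each as the mean of 4 arrays. The 20 Kupffer cell markers with a probe set had a median of 6.28, with Marco, a scavenger receptor, highest at 8.40. The 18 monocyte and monocyte-derived macrophage markers had a median of 6.16, with the fractalkine receptor gene Cx3cr1 highest at 7.50. The 1077 olfactory receptor genes, whose transcripts belong to sensory neurons, had a median of 6.19. Of 19046 protein-coding genes, 29 exceeded the 95th percentile of the negative controls, which was 11.6. The negative controls were no floor, since they reached 19.9. On each array their 95th percentile, 11.8 to 12.1, lay above that of the transcript clusters, 9.39 to 10.1, so the count of 29 is a strict one. The highest GC background control stood at 5.98 and 5.95 in fractions m and p after anti-CCL3 antibody, and at 6.31 and 5.90 after isotype control. Positive-control probe sets did not stand above negative ones on any array, with areas under the curve of 0.396 and 0.413 in fractions m and p after anti-CCL3 antibody and of 0.410 and 0.399 after isotype control, where chance gives 0.5. Eif2s3y, Kdm5d and Uty, single-copy Y genes that most male tissues transcribe, stood at 5.88, 5.93 and 5.98.

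Other classes had higher medians, which also lay within the distribution of the negative controls. The 30 mitochondrial probe sets had a median of 10.9, led by ND6, a subunit of respiratory complex I, at 17.9. The 50 Y-linked genes with many copies had a median of 10.4. The 914 small nuclear RNA genes had a median of 7.48 and reached 16.1. These medians stood at percentiles 93.3, 91.3 and 70.6 of the negative controls, and that of the abundant macrophage transcripts at 41.1. Probe sets differ in how well they bind their target, so these levels were compared as distributions and not probe set against probe set.

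**Figure D1:**
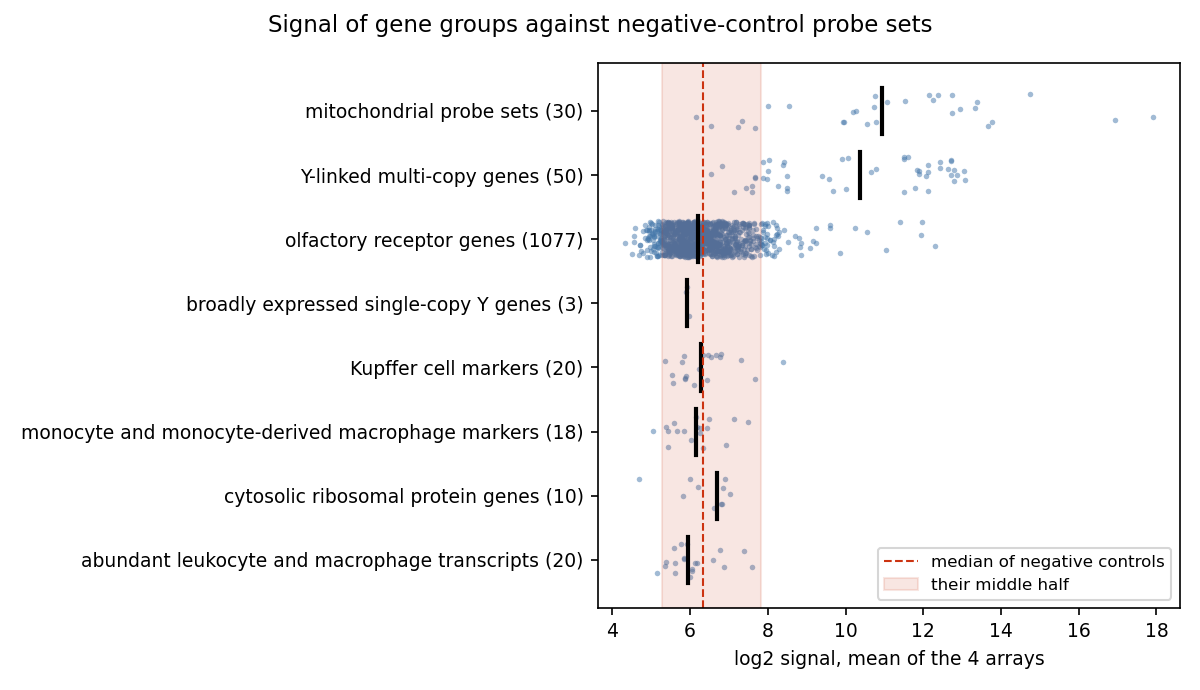
Signal of 8 gene groups, with the number of probe sets in each group after its name. Each point is 1 probe set, as the mean log2 signal of 4 arrays on the horizontal axis, and black bars are medians. The dashed line and the shaded band are the median and the interquartile range of the negative controls. The medians of mitochondrial probe sets, 10.9, and of Y-linked multi-copy genes, 10.4, lie to the right of the band, and the medians of the macrophage groups lie within it.

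The antibody's target and the sorting markers were read on each array. Ccl3 had signals of 7.80 and 7.64 in fractions m and p after anti-CCL3 antibody and of 7.99 and 7.44 after isotype control. The antibody difference was therefore -0.20 in fraction m and 0.20 in fraction p, with a fitted value of 0.00 ± 0.17 (SE, 4 arrays), which became -0.13 after quantile normalisation, -0.04 after median centring and -0.11 after cyclic loess normalisation. Ccr1, a receptor of CCL3, had a mean of 5.30 and lay below the level required for testing. Itgam, which encodes CD11b, had signals of 6.37 and 6.36 after anti-CCL3 antibody and of 6.18 and 6.15 after isotype control in fractions m and p. Adgre1, which encodes F4/80, had signals of 6.41 and 6.29 after anti-CCL3 antibody and of 6.50 and 6.54 after isotype control. Fractions p and m differed by -0.02 ± 0.11 (SE) in Itgam and by -0.04 ± 0.12 (SE) in Adgre1, and the sign turned after median centring for both, at 0.04 and 0.01, and for Itgam after quantile normalisation, at 0.00. Neither gene passed limma's test for fraction after Benjamini-Hochberg adjustment, with adjusted p of 0.981 and 0.954. Both had mean signals, 6.26 and 6.43, near the negative-control median of 6.34. On simulated data the test for fraction recovered 0.4% of genes that differed by 2 on the log2 scale. These values therefore do not show that the sorting markers are alike in both fractions.

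The comparison of anti-CCL3 with isotype control antibody asks how blocking this chemokine is reflected in hepatic macrophage RNA. Among the 12 genes named as higher after anti-CCL3 antibody in both fractions was Rps26, which encodes a protein of the small ribosomal subunit, read from a cluster on chromosome 12 although the gene lies on chromosome 10. This cluster had a log2 difference of 2.18 ± 0.15 (SE, 4 arrays), 2.02 in fraction m and 2.35 in fraction p. The cluster on the gene's own chromosome had 0.03, and the mean of the gene's 3 clusters 0.84. Retnla, a secreted product of alternatively activated macrophages, had a difference of 1.15 ± 0.21 (SE), with 0.87 in fraction m and 1.43 in fraction p. Its mean signal of 7.52 lay within the interquartile range of the negative controls, 5.27 to 7.84. The mitochondrial ribosomal RNA mt-Rnr1 differed by 1.15 ± 0.12 (SE), the secretoglobin gene Scgb2b12 by 1.35 ± 0.17 (SE) and the spermatid gene Sly, which has many copies on the Y chromosome, by 1.37 ± 0.25 (SE). After quantile normalisation mt-Rnr1 was at 0.40 and Sly at 0.63, and after cyclic loess normalisation they were at 0.72 and 0.77. The largest fitted value of the 12 belonged to mmu-mir-6371, at 3.72 ± 1.33 (SE), with 1.54 in fraction m and 5.90 in fraction p. The other genes named by the same rule were the small RNA genes Rn4.5s and AF357399, the keratin-associated protein gene Krtap21-1, the zinc finger genes Zfp640 and Zfp97, and Cdc42ep2, an effector of the GTPase Cdc42, with differences between 0.82 and 1.41.

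Of the 12 genes named as lower after anti-CCL3 antibody, Ighv8-13, a variable segment of the immunoglobulin heavy chain, had the most negative difference, -1.66 ± 0.11 (SE, 4 arrays), with -1.63 in fraction m and -1.70 in fraction p. An error of 0.11 is about the least that the prior allows and is not a measured spread between arrays. Arl14, a small GTPase, was at -1.63 ± 0.37 (SE), with -1.04 in fraction m and -2.21 in fraction p. Traj14, a joining segment of the T cell receptor alpha chain listed as a pseudogene, was at -1.29 ± 0.38 (SE), with -1.89 and -0.69. The other 9 were Krtap4-1, Krtap31-2, the placental prolactin family gene Prl3d2, the T cell receptor gamma segment Tcrg-V6, the beta-defensin gene Defb14, the kappa variable segment Igkv4-57, the trace amine receptor gene Taar9, Magea6 and the long noncoding RNA Platr26, with differences from -1.10 to -0.78. None of these 24 genes passed limma's test, with Benjamini-Hochberg adjusted p from 0.356 to 0.684. Over all 15071 tested genes the count at an adjusted p below 0.05 was 0, with 0.356 the smallest, and 1182 genes lay at an unadjusted p below 0.05, 974 higher and 208 lower, where chance gives 754. On simulated data of this layout the test recovered 0% of genes that differed by 1 on the log2 scale, 0.8% of those that differed by 2 and 66.4% of those that differed by 4.

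**Figure D2:**
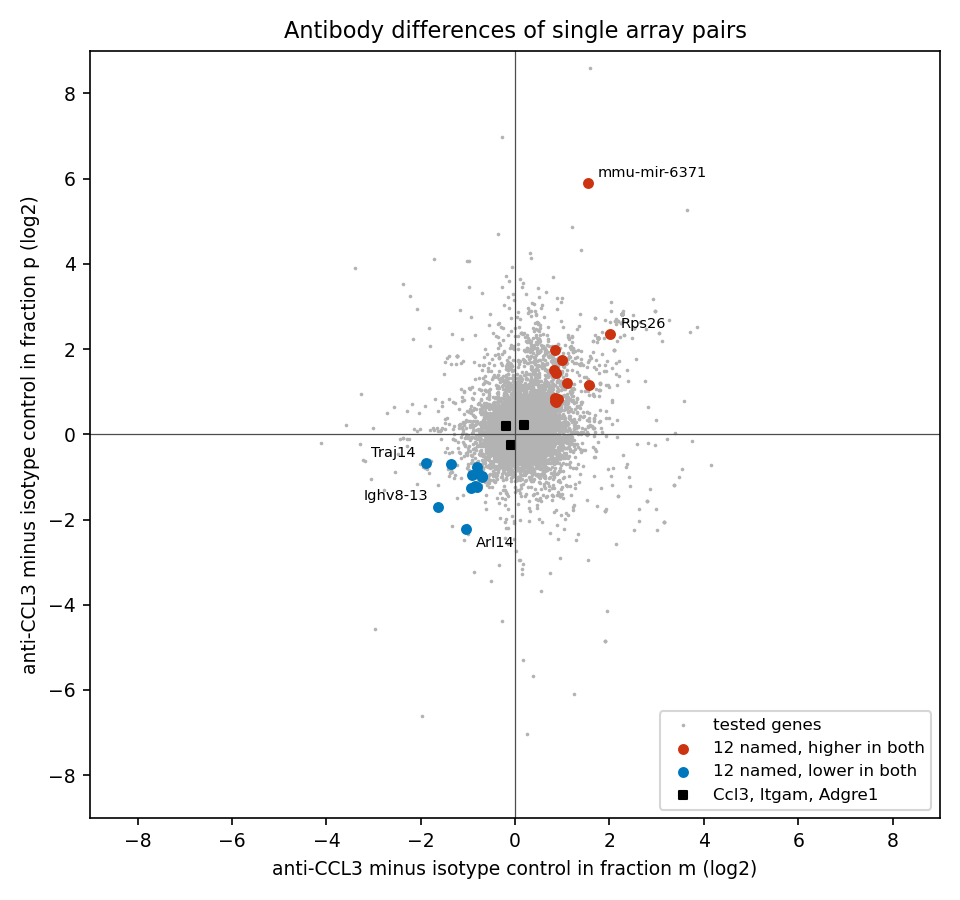
Log2 difference between the anti-CCL3 and the isotype control array in fraction m (horizontal axis) and in fraction p (vertical axis) for 15071 tested genes. Each grey point is 1 gene, red and blue points are the 12 genes named as higher and the 12 named as lower, and black squares are Ccl3, Itgam and Adgre1. The cluster named for Rps26 lies at 2.02 and 2.35 and Ighv8-13 at -1.63 and -1.70, and no gene passed the test.

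No gene list fixed for this tissue and treatment passed the test for antibody. Over all tested genes the median antibody difference was 0.04, and counts of higher and lower members are not corrected for this shift. Of 11 tested Kupffer cell markers, 3 were higher and 8 lower after anti-CCL3 antibody, with a median of -0.06, and of -0.14, -0.11 and -0.12 after quantile normalisation, median centring and cyclic loess normalisation. Clec2i and Clec1b were highest at 0.13 and 0.05, and Adgre1 and the folate receptor gene Folr2 lowest at -0.17 and -0.15. Clec1b was at 0.22 in fraction m and -0.11 in fraction p, and Folr2 at 0.23 and -0.52. Of 10 tested monocyte and monocyte-derived macrophage markers, 5 were higher and 5 lower, between Itgam and Ccr2, the receptor that draws monocytes from the bone marrow, at 0.20 and 0.15, and S100a4 and Gpr141 at -0.15 and -0.21. The 3 tested CCL3 ligands and receptors were Ccl3, Ccl4 and Ccl5, at 0.00, -0.04 and -0.09. Among 13 tested chemokine ligands, 7 were higher and 6 lower, with Ccl17 and Cxcl5 at 0.34 and 0.29, and Ccl11, an attractant of eosinophils, and Ccl2, an attractant of monocytes, at -0.46 and -0.44. Cxcl5 was at 0.59 in fraction m and -0.02 in fraction p, and Ccl2 at -0.75 and -0.13. The median of this list was 0.02 and turned to -0.09, -0.02 and -0.05 after quantile normalisation, median centring and cyclic loess normalisation.

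Genes of alternatively activated and tumour-associated macrophages were higher in 10 and lower in 5 of 15 tested members, with a median of 0.06, and of 0.02, 0.02 and 0.03 after quantile normalisation, median centring and cyclic loess normalisation. Retnla and Ccl17 were highest at 1.15 and 0.34, and the anti-inflammatory cytokine gene Il10 and the mannose receptor gene Mrc1 lowest at -0.46 and -0.15. Of 4 tested pro-inflammatory macrophage genes, Il1a stood at 0.44, Cd40 at -0.03, Tnf at -0.04 and Il23a at -0.16. Among 7 tested genes of the VEGF and lymphangiogenesis list, 3 were higher and 4 lower, between Angpt2 and Tie1 at 0.10 and 0.07, and Pdpn and Vegfa at -0.04 and -0.13. All 4 had opposite signs in fractions m and p, with -0.01 and 0.22 in Angpt2, -0.05 and 0.19 in Tie1, 0.24 and -0.33 in Pdpn, and 0.00 and -0.26 in Vegfa. Among 12 tested type I interferon response genes, 6 were higher and 6 lower, with Irf7 and Xaf1 at 0.23 and 0.15, and Ifi27l2a and Mx2 at -0.74 and -0.21. Over all 38 tested lists, medians ran from -0.09 for cholesterol and lipid handling genes to 0.14 for growth factors for macrophages and granulocytes. In limma's camera test 0 of 38 lists passed, with 0.858 the smallest Benjamini-Hochberg adjusted p, and 0 members passed when adjusted over the list alone. With an estimated correlation the smallest adjusted p was 0.983, and with fry it was 0.423.

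In the comparison of fraction p with fraction m, over both antibody groups, the 12 genes named as lower in fraction p included genes of the mitochondrial genome. The mitochondrial ribosomal RNA mt-Rnr1 was lower in fraction p by a log2 difference of -3.17 ± 0.12 (SE, 4 arrays), with -3.11 after anti-CCL3 antibody and -3.23 after isotype control. The complex I subunit genes ND3, ND6 and ND2 stood at -3.24 ± 0.18, -2.70 ± 0.15 and -1.46 ± 0.14 (SE), and COX2, a subunit of respiratory complex IV, at -1.97 ± 0.29 (SE). In fraction p COX2 had signals of 5.51 after anti-CCL3 antibody and 5.60 after isotype control, below the negative-control median of 6.34. A cluster on chromosome 14 annotated as Hspa8, a constitutive heat shock protein gene of chromosome 9, was at -2.94 ± 0.87 (SE), and none of the 4 clusters of that name lies on chromosome 9. The eosinophil-associated ribonuclease gene Ear14 was at -2.47 ± 0.67 (SE) and Cdc42ep2 at -1.61 ± 0.11 (SE). The receptor segments Igkv13-87 and Traj1, both listed as pseudogenes, the segment Trbv20 and the noncoding RNA Pmis2 lay between -2.82 and -1.55.

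The genes named for higher signal in fraction p included immunoglobulin and T cell receptor segments. The immunoglobulin segments Ighv3-1 and Ighv5-12-4 were at 1.54 ± 0.39 and 0.98 ± 0.13 (SE), Arl14 at 1.27 ± 0.37 (SE) and the glycosyltransferase gene B3gnt4 at 0.93 ± 0.12 (SE). Cd3d, a chain of the CD3 complex of T cells, was at 0.63 ± 0.11 (SE), with 0.59 after anti-CCL3 antibody and 0.67 after isotype control. Its mean signal of 6.49 lay within the interquartile range of the negative controls, 5.27 to 7.84, so it does not show T cells in fraction p. The T cell receptor segments Traj14, Traj38 and Traj59, the small cytoplasmic RNA Rny3, and Rnf133, Teddm3 and Zfp830 lay between 0.61 and 1.43, and Traj38, at 0.93, was at 1.58 after quantile normalisation and 1.59 after cyclic loess normalisation. None of these 24 genes passed limma's test, with Benjamini-Hochberg adjusted p from 0.396 to 0.539. The count over all 15071 genes was 0, with 0.396 the smallest adjusted p, and 1399 genes lay at an unadjusted p below 0.05, 255 higher and 1144 lower in fraction p, where chance gives 754. On simulated data the test for fraction recovered 0% of genes that differed by 1 on the log2 scale, 0.4% of those that differed by 2 and 72.4% of those that differed by 4.

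**Figure D3:**
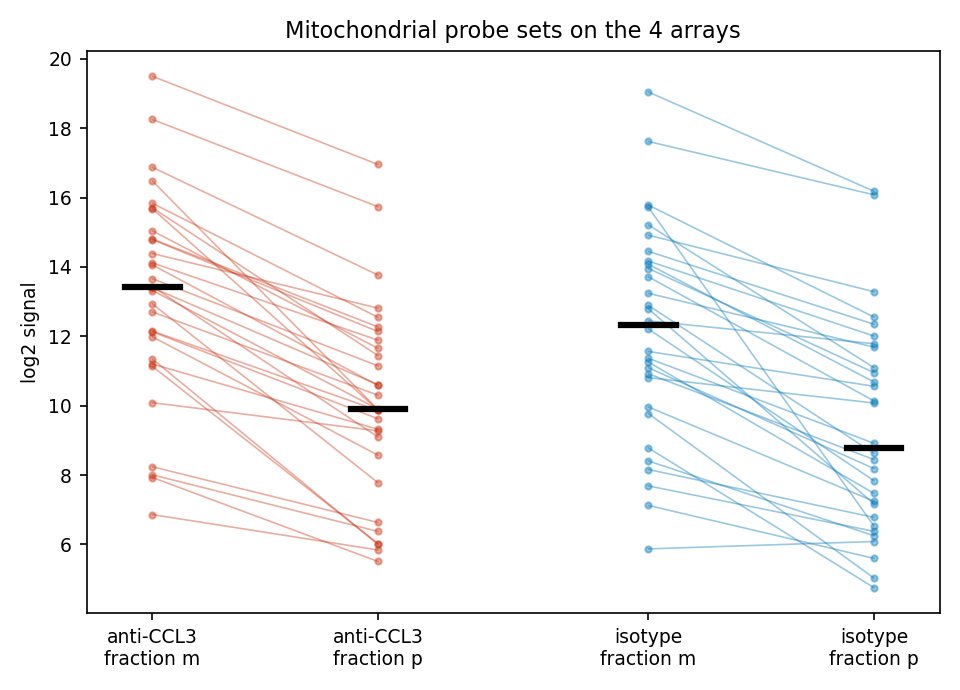
Log2 signal (vertical axis) of 30 mitochondrial probe sets on each of 4 arrays. Points are probe sets, lines join the same probe set in fractions m and p of an antibody group, red for anti-CCL3 antibody and blue for isotype control, and black bars are medians. In fraction p, 30 of 30 probe sets were lower after anti-CCL3 antibody and 29 of 30 after isotype control.

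Chemokine receptors were lower in fraction p in 6 of 6 tested members, with a median of -0.31. The most negative were Ccr7, which guides dendritic and T cells to lymph nodes, at -0.71 and the neutrophil receptor gene Cxcr2 at -0.44, and the least negative were Ccr2 at -0.10, with 0.04 after anti-CCL3 antibody and -0.24 after isotype control, and Ccr9 at -0.19. This list did not pass in limma's camera test, with a Benjamini-Hochberg adjusted p of 0.5, but it passed at 0.019 with 15 members and no filter on dim genes, and at 0.0447 among protein-coding genes alone. With an estimated correlation the adjusted p was 0.992, and in those other settings 0.982 and 0.953. Ccr7, Ccr9 and Xcr1 are also dendritic cell markers, a list higher in 2 and lower in 6 of 8 tested members, with a median of -0.23, Batf3 and Siglech highest at 0.09 and 0.02, and Ccr7 and Bst2 lowest at -0.71 and -0.44. Batf3 and Siglech were at 0.17 and 0.07 after anti-CCL3 antibody and at 0.00 and -0.03 after isotype control. The adjusted p of this list was 0.853, and 0.992 with an estimated correlation. NK cell markers were higher in 8 and lower in 3 of 11 tested members, with a median of 0.15, Xcl1 and Gzma highest at 0.57 and 0.41, and Klrb1c and Nkg7 lowest at -0.66 and -0.19. For NK cell markers the adjusted p was 0.5, and 0.992 with an estimated correlation.

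Over all tested genes the median difference between fractions p and m was -0.05, and counts of higher and lower members are not corrected for this shift. The medians of Kupffer cell, monocyte and T cell markers, given below, are about the same as this shift. Kupffer cell markers were higher in 3 and lower in 8 of 11 tested members in fraction p, between C1qc and Nr1h3 at 0.33 and 0.16, and Clec1b and Folr2 at -0.28 and -0.16. Folr2 was at -0.54 after anti-CCL3 antibody and 0.21 after isotype control. Their median of -0.04 turned to 0.02, 0.01 and 0.00 after quantile normalisation, median centring and cyclic loess normalisation. Monocyte and monocyte-derived macrophage markers were higher in 2 and lower in 8 of 10 tested members, with S100a4 and Lyz2 at 0.07 and 0.02, and Cx3cr1 and Ms4a4c at -0.34 and -0.23. Lyz2 was at 0.34 after anti-CCL3 antibody and -0.30 after isotype control. Their median was -0.05, and 0.01 after median centring. T cell markers were higher in 4 and lower in 7 of 11 tested members, with Cd3d and Cd8a at 0.63 and 0.15, and Cd8b1 and Bcl11b at -0.14 and -0.12. Their median of -0.05 turned to 0.02, 0.00 and 0.01 after quantile normalisation, median centring and cyclic loess normalisation. Neutrophil markers were higher in 4 and lower in 4 of 8 tested members, with Ly6g and Ngp at 0.54 and 0.10, and Stfa2l1 and Cxcr2 at -0.93 and -0.44, and Ly6g and Ngp were both at -0.21 after anti-CCL3 antibody and at 1.29 and 0.40 after isotype control. In total 0 of 38 lists passed for fraction, and 0 members passed when adjusted over the list alone.

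The antibody differences of both fractions were then set side by side. Across 15071 genes, which are not independent replicates, they correlated with Pearson's r of 0.215 and Spearman's rho of 0.141, and 53.4% of genes had the same sign in both. Among 8316 protein-coding genes r was 0.130. The fraction differences of both antibody groups correlated across genes with r of 0.181 and rho of 0.172, and 55.5% had the same sign. Fitted differences of at least 2-fold were seen for antibody in 699 genes and for fraction in 619. The interaction, which holds noise together with unlike responses, was taken as (antibody difference in fraction m minus that in fraction p) / 2. Noise that is independent between arrays thus enters it as it enters the antibody value. Differences in brightness between whole arrays can add up in the antibody and fraction values and cancel in the interaction. The interaction was at least 1 in size in 330 genes, a count that does not measure the part of such brightness differences in the 699 and 619. The antibody differences themselves were at least 2-fold apart between fractions in 1411 genes. Small nuclear and nucleolar RNA genes made up 395 of the 699, 334 of the 619 and 126 of the 330, and protein-coding genes 87, 72 and 43. The standard deviation over genes was 0.43 for antibody, 0.42 for fraction and 0.35 for the interaction on this scale. These differences grew with brightness, from medians of 0.03 and -0.01 in the dimmest decile of genes to 0.39 and 0.40 in the brightest decile for antibody in fractions m and p. Of the 699 genes, 613 (87.7%) were higher after anti-CCL3 antibody, a share of 66.3% after quantile normalisation and 73.1% after cyclic loess normalisation. Of the 619 genes, 83 (13.4%) were higher in fraction p, a share of 34.0% after quantile normalisation and 30.5% after cyclic loess normalisation.

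Within a fraction each antibody difference compares 2 arrays and has no replicate check. Kupffer cell markers had a median antibody difference of 0.09 in fraction m, at percentile 66.6 among 10000 random lists of equal brightness, and of -0.21 in fraction p, at percentile 0.89. Neutrophil markers had medians of 0.36 in fraction m and -0.10 in fraction p, at percentiles 99.03 and 12.3. Growth factors for macrophages and granulocytes had medians of 0.03 and 0.25, at percentiles 49.0 and 97.48. Genes of alternatively activated and tumour-associated macrophages had medians of 0.07 and 0.05, at percentiles 72.7 and 77.6. With 38 lists read in each fraction, extreme percentiles arise by chance as well.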

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

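The comparison of antibody differences between fractions was planned, and the mitochondrial sets were chosen after their values were seen. The genes in this part had opposite antibody differences in fractions m and p, each read from 1 array on either side, and the difference was not tested. Opposite signs are common here, since 53.4% of genes had the same sign in both fractions, and the genes were taken by a rule on the smaller of both differences, with Ccl3 added as the antibody's target.

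In 6 genes the signal after anti-CCL3 antibody was higher in fraction m and lower in fraction p. The antibody difference in fraction m minus that in fraction p was 2.60 in the ubiquitin-conjugating enzyme gene Ube2dnl1, 2.38 in the muscarinic receptor gene Chrm5 and 2.23 in Krtap19-3. It was 2.13 in Tex38, 2.08 in the kappa joining segment Igkj3 and 2.01 in a cluster on chromosome 3 annotated as Hnrnpa3, an RNA-binding protein gene of chromosome 2 without a cluster there. In 6 genes the order was the opposite, with -4.09 in the T cell receptor segment Traj47, -2.81 in the chromosome 14 cluster annotated as Hspa8, -2.10 in Igkv4-61, -1.78 in Cldn34b3, -1.49 in Tceal6 and -1.49 in Faiml. Ccl3, the antibody's target, had -0.40.

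Probe sets that the gene-level comparisons leave out were read as well. The 23 mitochondrial probe sets without a gene of their own had a median antibody difference of 0.64, and of 0.24 after quantile normalisation and 0.36 after cyclic loess normalisation. In fraction m the median was 0.76, at percentile 99.8 among 10000 random lists of equal brightness, whose median was 0.36. In fraction p it was 0.40, at percentile 38.9, with 0.48 in random lists, so there it did not exceed probe sets of equal brightness.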

How the results depend on the processing

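Cyclic loess normalisation, protein-coding genes alone and leaving out clusters on another chromosome than the gene were chosen after the data were seen, and the other settings were planned. The count of genes at an adjusted p below 0.05 (limma, Benjamini-Hochberg) was 0 for antibody and 0 for fraction in each of 16 alternatives, with 499 to 2390 and 523 to 2965 genes at an unadjusted p below 0.05. These include the fits without the fraction or antibody term and those with 1 array left out, in which the lone array of a group is assumed to vary like the others. On simulated data the main fit recovered 0.8% of genes that differed by 2 on the log2 scale for antibody and 0.4% for fraction. A count of 0 in each setting was therefore likely in advance and does not show that genes are unchanged. Leaving out an array with both terms in the fit leaves no degree of freedom, so the named genes then have values and no test. Gene lists gave 0 calls for antibody in 13 alternatives. For fraction the chemokine receptors passed without the filter on dim genes (1 list, adjusted p 0.019) and among protein-coding genes alone (1 list, 0.0447), within a range of the smallest adjusted p from 0.019 to 0.992. With an estimated correlation the chemokine receptors had 0.982 and 0.953 in these settings, and the cause was not tested.

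The correlation of antibody differences moved to 0.135 after quantile normalisation, 0.139 after cyclic loess and 0.130 in protein-coding genes. Genes at least 2-fold apart numbered 463 after quantile normalisation, 457 after cyclic loess and 87 among protein-coding genes for antibody, 407 after cyclic loess and 72 among protein-coding genes for fraction, and 43 protein-coding genes had an interaction, (antibody difference in fraction m minus that in fraction p) / 2, of at least 1 in size. The last counts cover fewer genes by construction, and the cause of the others was not tested. Signs turned for Ccl3 with antibody (-0.128 after quantile normalisation, -0.0412 after median centring, -0.111 after cyclic loess), for Adgre1 with fraction (0.0128 after median centring) and for Itgam with fraction (0.000132 after quantile normalisation, 0.0364 after median centring), and the cause was not tested. The other named genes kept their sign under these scalings, as did the difference between fractions in the 12 genes with opposite antibody differences, but sizes moved. Rps26 with antibody was at 0.84 with the mean of its probe sets and 0.03 without clusters on another chromosome. That last setting leaves no value for Hspa8 and Hnrnpa3. After quantile normalisation mt-Rnr1 with antibody was at 0.40, Sly with antibody at 0.63 and Traj38 with fraction at 1.58. In fraction m alone, 24 of 54 antibody differences moved by more than 1.5 times, 6 of them to the opposite sign, and in fraction p alone 24 moved, 2 of them to the opposite sign. Of 53 fraction differences, 24 moved after anti-CCL3 antibody alone and 28 after isotype control alone, 3 and 5 of them to the opposite sign. The 24 genes named for antibody and the 24 named for fraction were chosen for the same direction in both pairs. With 1 pair alone they could not turn sign in that contrast, so the turns fell among the other genes. Signal over background limits all comparisons, since the medians of the macrophage groups lay below the median of the negative controls.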

Other observations

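The gene lists, the limma fit and the 2-fold counts were planned, and the tests of explanations and the mitochondrial sets were chosen after the values were seen. Markers of other cells that a liver sort could hold had levels like those of the macrophage lists. Hepatocyte markers had a median signal of 6.12, with Ahsg, which encodes the plasma protein fetuin-A, highest at 7.11. Liver sinusoidal endothelial cell markers had a median of 5.88, hepatic stellate cell and fibroblast markers 5.97, epithelial and carcinoma cell markers 5.99 and erythroid markers 6.49. The glycolytic gene Gapdh, at 9.96, was the brightest member of any list, and its fraction difference was -0.63 ± 0.11 (limma SE, 4 arrays).

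Mitochondrial probe sets separated the fractions in both antibody groups. Their median difference between fractions p and m was -2.59 after anti-CCL3 antibody and -2.59 after isotype control, and it was -2.31 and -2.17 after quantile normalisation and -2.31 and -2.12 after cyclic loess normalisation. The antibody difference had a median of 0.74 in fraction m, beyond 10000 random lists of equal brightness, and of 0.40 in fraction p, at percentile 47.0 of such lists. After cyclic loess normalisation these medians were 0.40 and 0.03. Probe sets of a single small genome can vary together, unlike those of random lists. The percentiles can therefore overstate how unusual the values are, and each difference compares 2 arrays.

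Abundant leukocyte transcripts lay at the level of negative controls. Values attached to the wrong probe sets over the whole table are argued against, because the signals of 2 clusters of the same protein-coding gene correlated over 135 genes with Spearman's rho of 0.335, and the highest of 10000 shuffles gave 0.295. A mismatch in part of the table is not excluded by this. A failed hybridisation or scan is argued against as well, because the control cre exceeded bioB by at least 3.69 on the log2 scale on each array. These hybridisation controls do not test the steps before, such as amplification and labelling. The further spike controls lys, phe, thr and dap lay between 3.52 and 4.59 on the 4 arrays, below the negative-control median of 6.34. Whether they were added to the samples is not known here, so a failure of those earlier steps stays open and was not tested. Signal that follows the number of copies of a sequence in the genome, from genomic DNA or from unrelated RNA, and the sequence composition of the probes stay open and were not tested, since copies and probe sequences were not at hand.

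Mitochondrial probe sets were lower in fraction p than in fraction m. Dimmer bright probe sets on the p arrays do not account for this, since the median difference lay below that of random lists of equal brightness in both antibody groups, by -2.05 in the group with the smaller gap. A difference in mitochondrial content between the cells of both fractions, which the design names, and a difference in the amount or quality of RNA stay open and were not tested. Whether the mitochondrial signal came from RNA or from DNA was not tested either.

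More genes had an antibody value of at least 1 in size than an interaction value of that size, with the interaction taken as (antibody difference in fraction m minus that in fraction p) / 2, and the excess was 369. A candidate explanation is a difference in scale of bright probe sets between the arrays. A single dim array would enter antibody and interaction values alike. The 95th percentile of the transcript clusters was 10.1 and 9.77 in fractions m and p after anti-CCL3 antibody, and 9.74 and 9.39 after isotype control. With the brightest and the dimmest array in opposite groups, such differences add up in the antibody and fraction values and largely cancel in the interaction. After cyclic loess normalisation the excess was 145, so 60.7% of it was removed. Whether the rest comes from the antibody cannot be told apart from differences between arrays, because each combination had 1 array.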
